A study of Oryza sativa with 6 samples.

How the data were processed

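Messenger RNA of rice (Oryza sativa) roots was measured by strand-specific RNA sequencing. Total RNA had been extracted from 3 root types of 2 cultivars, which gave 6 libraries, 1 for each cultivar and root type. Per the labels' protocols the plants grew at set day and night temperatures and humidity, and no salt treatment is named for any of the 6 libraries. Per the submitters' processing notes, Trimmomatic 0.32, Bowtie, TopHat2 2.0.11, Cufflinks 2.2.1 and Cuffdiff 2.2.1 were used with the IRGSP-1.0 genome build. Their options, the annotation behind the loci and the handling of strand and of reads with several alignments are not given in the sources used here, so that reads shared between near-identical or overlapping loci could not be assessed.

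The authors deposited 1 table of 38042 loci with, for each library, a scaled fragment count, 3 variance columns and a status flag, per the file headers. The deposited values are a signal per locus: fragment counts that were multiplied by 1 scaling factor per library before deposit, as the values themselves show. In each library 100% of the values above 0 were whole multiples of 1 step, with a tolerance of 0.1 of a read, and the largest gap from a whole number was 0.0772 of a read. A read was worth between 0.601 units in the Mulai nodal library and 1.50 units in the IR29 S-type library. Division by the step recovered whole reads, whose totals ranged from 3891153 in the IR29 L-type library to 7904454 in the Mulai nodal library. The 24 variance and status columns were not used.

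The loci carry only identifiers that were made during assembly or quantification. None of the 38042 identifiers is paired with a gene name in the table, and 0 of them matched the 39387 rows of the RefSeq gene table that was available (assembly ASM3414082v1). Gene names, coordinates, length and GC content were therefore not used. The 38 gene lists fixed before the data were examined, which covered ion and water transport, cell walls, hormones, stress responses and shoot markers, could not be applied. The rule for naming genes required an informative name. It was replaced by the same ranking without names, limited to 2 loci in each direction in the comparison of S-type with nodal roots: the largest change among loci with adjusted p under 0.05, a mean value of at least 100 and the same direction in both cultivars.

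Because the deposited values were scaled, the main test was made on the log scale, as the design fixed before the data were examined had provided for. Loci with a value of at least 10 in at least 2 libraries were kept, 20316 in all. Values were transformed to log2(value + 1), so that fold changes lie on that scale and understate the change of low loci. An additive model with cultivar and root type was fitted to all 6 libraries with limma 3.58.1 (R 4.3.3), with moderated variances that followed a trend on the mean expression. Adjusted p-values are those of Benjamini and Hochberg, with a threshold of 0.05. Each cultivar and root type had 1 library. The only replication of a root type was therefore that both cultivars contributed a library, and the spread against which differences were judged contained library noise and any difference of root type effects between the cultivars. The model left 2 residual degrees of freedom. The labels do not say whether libraries came from separate plants or pools, and the p-values measure only the spread between these libraries. The interaction of cultivar and root type had no residual degree of freedom. It is described with values and a size rule and no test. The labels refer the 3 Mulai libraries and the 3 IR29 libraries to separate earlier sets of records, so that cultivar is confounded with any batch of growth, library preparation or sequencing.

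The procedure was tested on simulated data drawn from the real means and depths, with the dispersion trend fitted to the real libraries. Each simulation held 200 changed loci, all drawn from loci with a mean value of at least 50. For S-type against nodal roots over 19690 loci, it called 2% of the loci changed 2-fold, 48% of those changed 4-fold, 98% of those changed 16-fold and 100% of those changed 64-fold, with 2 unchanged loci called. For IR29 against Mulai over 19662 loci, the shares were 12%, 82%, 100% and 100%, with 4 unchanged loci called. Every locus took its dispersion from the trend, and no separate difference of root type effects between the cultivars was simulated. Far fewer loci were changed than were called between S-type and nodal roots in the real data. The shares and false calls hold for this setting and may not carry over to the real libraries.

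The alternatives fixed in advance were edgeR 4.0.16 (quasi-likelihood test, TMM) and DESeq2 1.42.0 on the recovered reads, TMM and median ratio scaling, pseudocounts of 0.5 and 5, no filter and a filter at 50, a model without the other factor, and leaving out each library. Thinning of the reads of every library to the smallest total was added after the depths were seen. Counts of loci past 2-fold in single libraries, cultivar folds within a root type and the division of called loci by their reads in each cultivar were also chosen after the data were seen. Intervals on counts and floors (3 reads for a count of 0) cover counting error only. Intervals on correlations and medians across loci come from 1000 resamplings of loci, which are not independent replicates.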

Results

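Transcripts were measured in nodal roots, which emerge from the stem nodes, and in both classes of lateral roots of rice: S-type laterals, which are short, thin and unbranched, and L-type laterals, which are longer and branch again. Each root type was sampled in the cultivar Mulai, labelled salinity tolerant, and in IR29, a cultivar commonly used as a salinity sensitive standard. The 6 libraries held 1 library per cultivar and root type, with no replicate. The Mulai libraries held 7904454 reads (nodal), 6246649 (S-type) and 5631504 (L-type), and the IR29 libraries 4253677, 4083173 and 3891153 in the same order, so that every Mulai library was deeper than every IR29 library. Between 22186 and 25620 of the 38042 loci had at least 1 read in a library. The 100 most abundant loci took 14.68% of the reads in the Mulai S-type library (exact 95% binomial interval 14.65 to 14.71) and 14.64% in the IR29 S-type library (14.61 to 14.68). In the L-type libraries they took 11.005% (Mulai, 10.98 to 11.03) and 10.66% (IR29, 10.63 to 10.69), and in the nodal libraries 12.15% (Mulai, 12.13 to 12.17) and 13.92% (IR29, 13.89 to 13.95).

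The first principal component of the 20316 tested loci (46.7% of the variance) parted Mulai from IR29, and the second (34.2%) ordered the root types from nodal through L-type to S-type in both cultivars. The third component (11.3%) set the IR29 L-type library at -96.5, against 71.8 for the IR29 S-type and 52.2 for the IR29 nodal library, while the Mulai libraries lay between -17.1 and 5.96. Within Mulai, the L-type library correlated with the nodal library at r = 0.90 and with the S-type library at r = 0.91 across loci, above the r = 0.78 between nodal and S-type. Within IR29 the corresponding values were 0.83, 0.84 and 0.74. Across cultivars, the nodal libraries correlated at r = 0.80, the S-type libraries at r = 0.79 and the L-type libraries at r = 0.71. The Mulai L-type library correlated more with the IR29 S-type (r = 0.74) and IR29 nodal (r = 0.72) libraries than with the IR29 L-type library.

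**Figure D1:**
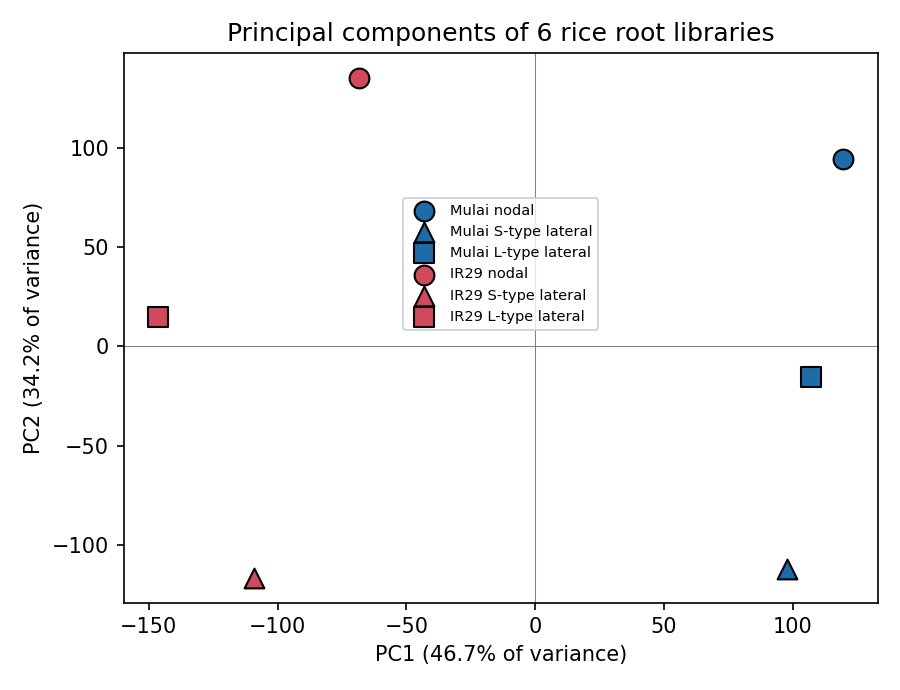
Scores of the 6 libraries on the first and second principal components of log2(scaled count + 1) over 20316 loci, with 1 point per library, colour for cultivar and marker shape for root type. Mulai and IR29 lie on opposite sides of the first component, and in both cultivars the L-type library lies between the nodal and the S-type library on the second.

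S-type lateral roots were compared with nodal roots to ask which transcripts distinguish the short laterals from main roots. In S-type roots 2129 loci were higher and 2074 lower than in nodal roots, 4203 of 20316 tested (20.7%; limma, adjusted p under 0.05, 2 libraries per root type, 1 from each cultivar). The median change of the called loci was 2.32 on the log2 scale, or 2.28 with every value under 3 reads set to 3 reads, and 2536 of them changed 4-fold or more. At an unadjusted p under 0.05 there were 7526 loci, against 1016 by chance. The tests on recovered reads called 3630 loci (edgeR) and 4935 loci (DESeq2), of which 3574 and 4036 were among the 4203. The count fell when any nodal or S-type library was left out. Such a fit leaves a lone library on a side of this comparison, so that a lower count was likely beforehand. The fall therefore does not show that the count rested on the library left out. The count was also lower, at 1589 loci, when cultivar was left out of the model, and it was higher when either L-type library was left out.

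The loci with the largest changes were close to absent in one root type. They are given by identifier because the table pairs no gene names with them. XLOC_033938 rose from a scaled count of 16.8 in Mulai nodal roots to 46757 in Mulai S-type roots, where it was supported by 52538 reads, and from 3.46 to 10039 in IR29. This was a ratio of 2780 in Mulai (95% counting interval 1920 to 4180) and 2900 in IR29 (993 to 14100), with a fitted log2 change of 11.25 ± 0.38 (SE, adjusted p = 0.00175, limma). XLOC_008562 rose from 4.81 to 27600 in Mulai and from 3.46 to 1860 in IR29, a ratio of 5740 in Mulai (2910 to 13300) and of 538 in IR29 (184 to 2610), with a fitted log2 change of 10.46 ± 0.76 (SE, adjusted p = 0.00408, limma). In the other direction, XLOC_002289 had scaled counts of 947 in Mulai nodal and 1373 in IR29 nodal roots (adjusted p = 0.00289, limma). It had no read in either S-type library. With 3 reads per library taken as the floor, it was 355-fold lower in Mulai and 304-fold lower in IR29. The lower ends of the 95% counting intervals of these ratios were 288 in Mulai and 247 in IR29. XLOC_007463 fell from 2627 to 0.890 (1 read) in Mulai and from 3470 to 4.51 (3 reads) in IR29, a ratio of 2950 in Mulai (529 to 117000) and of 769 in IR29 (263 to 3730), with adjusted p = 0.00408 by limma. The loci were chosen for their S-type and nodal extremes, which leaves little room for an L-type value outside them. For XLOC_033938 the L-type value was 1138 in Mulai and 111 in IR29, and for XLOC_007463 it was 159 in Mulai and 52.7 in IR29.

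**Figure D2:**
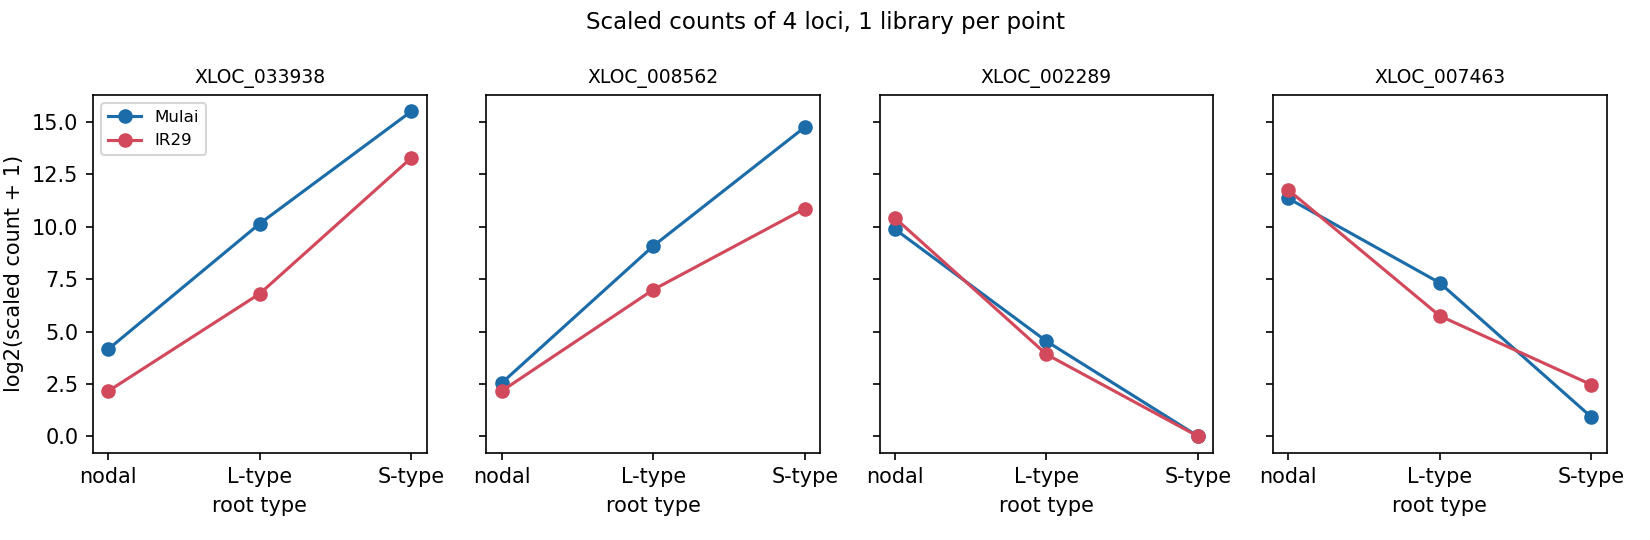
log2(scaled count + 1) of the loci with the largest rise (XLOC_033938, XLOC_008562) and fall (XLOC_002289, XLOC_007463) from nodal to S-type roots, by root type, with 1 line per cultivar and 1 library per point. The loci were chosen for the difference between S-type and nodal roots, and XLOC_002289 is at 0 in both S-type libraries.

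L-type lateral roots were compared with nodal roots in the same model. Only 12 of 20316 loci passed, 10 of them higher and 2 lower in L-type roots, each by a log2 change of at least 3.23 (limma, adjusted p under 0.05). The unadjusted count was 3896 loci, against 1016 by chance. The median absolute log2 change over all loci was 0.54, against 0.83 for S-type over nodal with the same standard error. The number of called loci depended on the test: edgeR called 0, with 3669 at an unadjusted p under 0.05, and DESeq2 called 1298, of which 683 were higher and 615 lower. It was 0 without either nodal library or without the IR29 L-type library, 633 without the Mulai S-type (368 higher, 265 lower) and 698 without the IR29 S-type library (391 higher, 307 lower). Without the Mulai L-type library it was 993, and most of these loci were lower in L-type roots (269 higher, 724 lower).

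The lateral root types were compared with each other to ask whether long and short laterals differ. No locus passed in limma (smallest adjusted p = 0.0508), with 3801 loci at an unadjusted p under 0.05 against 1016 by chance. edgeR also called 0 loci, with 3425 at an unadjusted p under 0.05, and DESeq2 called 1033 loci, 365 higher and 668 lower in L-type roots. In limma 390 loci were called without the Mulai L-type library, 8 without the Mulai S-type, 8 without the IR29 S-type and 3 without the Mulai nodal library, and 0 without either of the other libraries.

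IR29 was compared with Mulai over all root types, with 3 libraries of each cultivar, each from a different root type. These libraries are not replicates of a cultivar. The p-values judge the cultivar difference against library noise and its own variation across root types. The labels do not say whether the libraries came from separate plants, so that variation between plants of a cultivar could not be assessed. IR29 differed from Mulai in 1500 loci, of which 582 were higher and 918 lower in IR29 (limma, adjusted p under 0.05). The median fitted change of the called loci was 4.31 on the log2 scale, and 3.21 with every value under 3 reads set to 3 reads, at which 1234 of them changed 4-fold or more. Of the 1500 loci, 936 had 3 or fewer reads summed over the libraries of one cultivar. edgeR called 1092 loci and DESeq2 2031. With a filter at 50 in place of 10 the count was 726. The cultivar difference cannot be told apart from a batch, since each cultivar comes from its own earlier set of records.

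**Figure D3:**
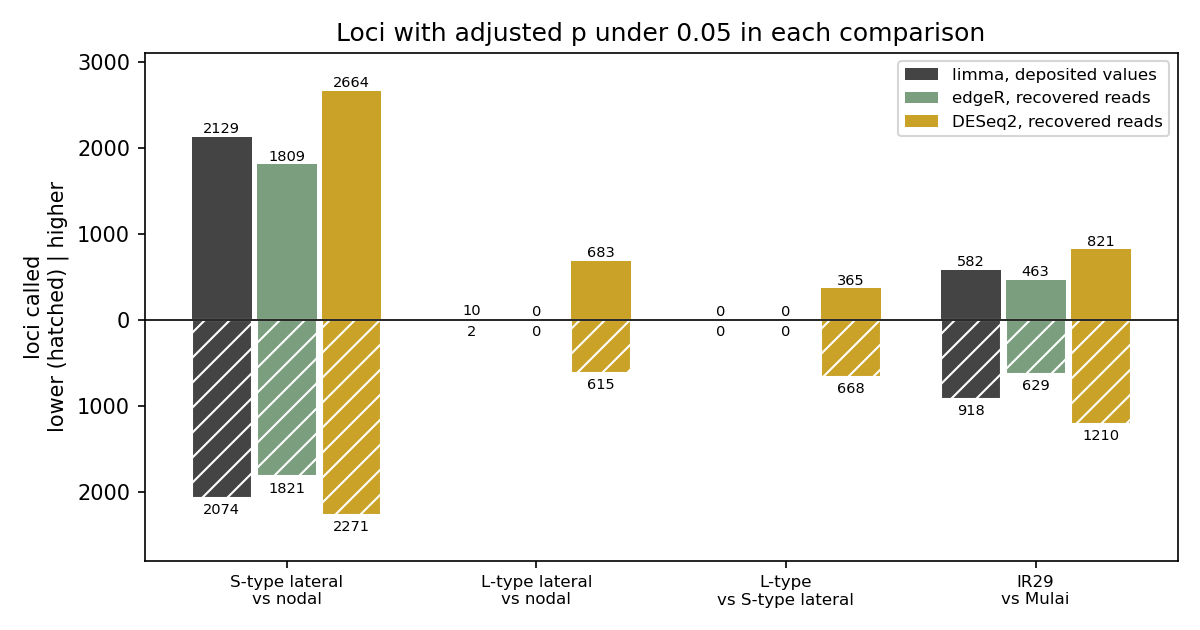
Number of loci called higher (solid bars above 0) and lower (hatched bars below 0) at adjusted p under 0.05 in each of the 4 comparisons, by limma on the deposited values and by edgeR and DESeq2 on recovered reads. S-type against nodal gives the highest counts with each tool (4203 loci by limma), and the counts for both L-type comparisons range from 0 in edgeR to 1298 and 1033 in DESeq2.

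Differences between the cultivars were smallest in the nodal and largest in the L-type libraries. The median absolute log2 fold of IR29 over Mulai was 0.38 in nodal, 0.54 in S-type and 0.80 in L-type roots. In L-type roots 5240 loci were at least 2-fold lower and 3056 at least 2-fold higher in IR29. In nodal roots these counts were 2720 and 1552, and in S-type roots 2844 and 2986. Each of these values compares 1 library with 1 library and has no test, and the IR29 L-type library stood apart on the third principal component. Across all 3 root types, 1200 loci were at least 2-fold lower and 775 at least 2-fold higher in IR29.

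The title of the study sets root types against salinity tolerance, and the folds of one root type over another were therefore compared between the cultivars, each fold coming from separate libraries. Tolerance was represented by Mulai alone and sensitivity by IR29 alone, and no salt treatment is named. A difference between them therefore cannot be assigned to tolerance. The S-type over nodal folds agreed in part between the cultivars. They correlated at r = 0.77 (resampled interval 0.76 to 0.78) and rho = 0.76 across 20316 loci, and 77.1% of loci had the same sign. The remaining loci include those with a fold of exactly 0 in a cultivar, so that not all of them moved in opposite directions. At least 2-fold higher in S-type roots were 4023 loci in Mulai and 4825 in IR29, and 2925 were higher in both, where independent lists would share 955. At least 2-fold lower were 4521 and 4758 loci, with 3242 in both against 1059. The L-type over nodal folds correlated at r = 0.55 (0.53 to 0.56) and rho = 0.50, with 1244 loci higher in both against 423, and 1325 lower in both against 416. The L-type over S-type folds correlated at r = 0.32 (0.30 to 0.34) and rho = 0.30. Mismatched folds gave r = 0.53 for S-type over nodal in Mulai with L-type over nodal in IR29, and r = 0.71 for L-type over nodal in Mulai with S-type over nodal in IR29, above the r = 0.55 of the matched L-type folds. Genes are not independent replicates, and no p-value is given.

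**Figure D4:**
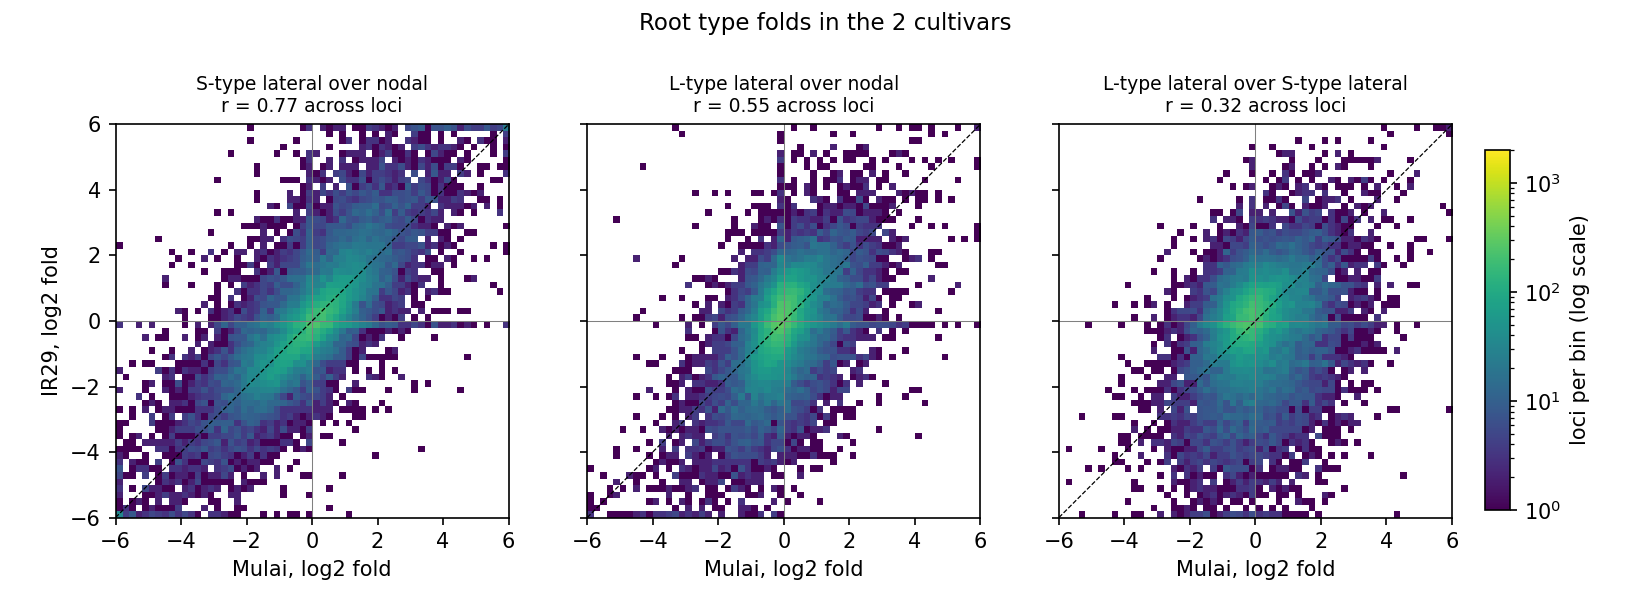
Log2 folds of one root type over another in Mulai (horizontal axis) and in IR29 (vertical axis) for 20316 loci, counted in squares of 0.2 log2 units with a log colour scale. Folds beyond 6 are drawn at the edge, and the dashed line marks equal folds. The loci lie closest to the line for S-type over nodal (r = 0.77) and most widely for L-type over S-type (r = 0.32).

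The number of loci past 2-fold between root types also differed between the cultivars. L-type and nodal libraries differed at least 2-fold in 4241 loci in Mulai (20.9%) and in 8129 loci in IR29 (40%), while S-type and nodal libraries differed in 8544 (42.1%) and 9583 (47.2%). The IR29 L-type library was the shallowest of all (3891153 reads) and stood apart on the third principal component. These 2-fold counts were not repeated on reads thinned to equal depth, so that counting noise may account for a part of the difference. By the size rule fixed in advance, a difference of at least 2 log2 units between the cultivars' folds, the S-type over nodal fold differed in 1239 of 15791 eligible loci (7.85%), with 896 higher and 343 lower in IR29. The L-type over nodal fold differed in 1200 of 15507 loci (7.74%), with 300 higher and 900 lower in IR29. The L-type over S-type fold differed in 2027 loci (13.1%), with 420 higher and 1607 lower in IR29. With 1 library per cultivar and root type, these differences have no replicate check and were not tested. With a value of at least 200 in place of 50 required in 1 of the libraries, the counts were 594, 471 and 934. Because 1 library sufficed, a locus with few or no reads in a cultivar was also eligible. Without reads it shows no fold in that cultivar, and a fold of at least 2 log2 units in the other meets the rule. Such loci were not counted apart. These counts therefore cannot tell a different root type response from a locus that was not detected in a cultivar.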

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

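The counts of loci past 2-fold were chosen after the data were seen, and the tests of counting noise and swapped labels after the pattern they bear on was seen, but before their own results. Some loci moved at least 2-fold in opposite directions in the 2 cultivars. For S-type over nodal roots there were 229 such loci, where independent lists would give 2016: 60 were higher in S-type roots in Mulai and lower in IR29, and 169 the reverse. For L-type over nodal roots there were 324 (independent lists 859), of which 235 were higher in L-type roots in Mulai and lower in IR29. For L-type over S-type roots there were 794 (independent lists 1110), of which 648 were higher in L-type roots in Mulai and lower in IR29. These differences were not tested, since each fold rests on 1 library per root type.

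The folds of L-type over nodal roots agreed less between the cultivars (r = 0.55) than those of S-type over nodal roots (r = 0.77). Among the 2467 loci with a mean scaled count of at least 500, the correlations were 0.73 and 0.88. The difference of 0.148 (resampled interval 0.122 to 0.175) argues against counting noise at low expression as the whole cause. It was smaller than the difference over all loci, so that counting noise may account for a part. A filter on the mean over all 6 libraries also does not keep out a locus with few reads in 1 of them. Swapped root type labels among the IR29 libraries were also argued against, since 0 of the other 5 assignments of these libraries gave a smaller residual sum of squares than the labelled one, and the nearest gave 1.54 times as much. A difference of the cultivars in their L-type roots, a difference in the age or part of the roots sampled, and an IR29 L-type library of another origin stay open, as untested.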

How the results depend on the processing

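The test on thinned reads was chosen after the data were seen. The alternatives below moved counts by over 1.5 times or correlations beyond their resampled interval, and the cause was not tested. For L-type against nodal roots (12 loci), edgeR gave 0 (3669 at an unadjusted p under 0.05), DESeq2 1298, a pseudocount of 5 gave 82, no filter 130, and a model without cultivar 0. For L-type against S-type roots (0 loci), DESeq2 gave 1033, no filter 20, the filter at 50 gave 2, and thinned reads 2. For S-type against nodal roots (4203 loci) the model without cultivar gave 1589. For IR29 against Mulai (1500 loci) the filter at 50, which tested 14707 loci, gave 726. Leaving out each library in turn gave 73 to 6096 loci for S-type against nodal, 0 to 993 for L-type against nodal and 0 to 390 for L-type against S-type, and kept IR29 against Mulai within 1046 to 1690. A fit without one library leaves 1 root type with a lone library that is assumed to vary like the others. These counts therefore do not show which library a result rests on. The correlation of S-type over nodal folds (0.768) was 0.780 with a pseudocount of 5, 0.821 with the filter at 50 and 0.757 in thinned reads. That of L-type over nodal folds (0.545) was 0.565 with a pseudocount of 5 and 0.601 with the filter at 50, and that of L-type over S-type folds (0.32) was 0.355 with the filter at 50. With a minimum of 200 in place of 50, the loci whose fold differed between cultivars by the size rule numbered 594 (S-type over nodal), 471 (L-type over nodal) and 934 (L-type over S-type). The other 61 values of these results stayed within 1.5 times or within the resampled interval, and the 4 loci given by identifier kept their direction and stayed under the threshold in all 64 of their values under the alternatives. These loci were chosen as the largest changes in the same libraries, so that their stability was likely beforehand. Root types were paired within a cultivar by the cultivar term of the model, and the model without it gave the 1589 and 0 loci above. Replicate numbers gave no further pairing, since the groups share fewer than 2 of them. The planned gene list tests and their alternatives were not run, since the loci carry no gene names.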

Other observations

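The tests of the L-type position and of a mixture, the counts of loci extreme in 1 root type and the thinning of reads were chosen after the data were seen. For the 9583 loci that differed at least 2-fold between S-type and nodal roots in IR29, the median log2 change from nodal to L-type in Mulai was 51.1% of that from nodal to S-type (resampled interval 50 to 52.4). For the 8544 loci chosen in the same way in Mulai, it was 55.8% in IR29 (53.4 to 58.1). These pooled values were not split by direction, but a smaller set with larger changes was. Among loci that differed 8-fold or more in both cultivars, the median L-type value in IR29 lay 42.1% of the way from nodal to S-type where S-type was higher, and 27.5% of the way from S-type to nodal where nodal was higher. In Mulai these values were 55% and 50.2%. Few loci had their extreme in L-type roots of Mulai: 217 lay at least 2-fold above and 72 at least 2-fold below both other root types (1.95% of 14853 loci with a value of at least 50 in 1 of the Mulai libraries). In IR29 these counts were 557 and 1136 (11.2% of 15101 loci). By the same rule the extreme lay in S-type roots for 19.9% of loci in Mulai and 22.5% in IR29. It lay in nodal roots for 15.4% in Mulai and 23.6% in IR29. Among the 13656 loci eligible in both cultivars, 601 were highest in nodal roots by 2-fold in both, where independent lists would share 84.7, and 638 were highest in S-type roots in both, against 162. In L-type roots 20 loci were highest in both cultivars, against 4.27, and 25 lowest, against 4.31. Independent lists assume that every locus is equally likely to pass, so that an excess over them is no test of a shared root type pattern.

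An L-type library between the others on the log scale could come from root material that held both nodal and S-type tissue. A mixture would add linearly, so that the share of the S-type level reached by loci high in S-type roots and the share of the nodal level reached by loci high in nodal roots would sum to about 100%. In Mulai the median shares were 22.6% over 339 loci and 16.6% over 282 loci that differed 8-fold or more in both cultivars, a sum of 39.2% (resampled interval 36.5 to 42.2). In IR29 they were 9.88% and 5.03%, a sum of 14.9% (12.3 to 17.8), so that a mixture of these 2 root types as the whole cause is argued against in both cultivars. The loci were chosen in part by the S-type and nodal values of the cultivar that was measured. This choice lowers both shares by an amount that was not measured. No biological explanation was tested.

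More of the called loci were lower (918) than higher (582) in IR29. The shallower IR29 libraries are argued against as the cause: with the reads of all libraries thinned to 3891153, 39.6% of the called loci were higher in IR29 (median of 20 thinnings, 38.8 to 40.1), close to the 38.8% of the full data. Without the loci that had 3 or fewer reads in a cultivar, 281 called loci were higher and 283 lower in IR29. This was 49.8% higher (exact 95% binomial interval 45.6 to 54.0). Of the 936 called loci with 3 or fewer reads in 1 cultivar, 301 were higher and 635 lower, so that nearly all of the excess lay among them. The change itself decides which loci fall in this set, and the reads were not thinned, so that the cause of the excess stays open. In the thinned reads a median of 392 loci had no read in any IR29 library (0 of 11673459 reads, which allows 3) and at least 10 reads in each Mulai library, and 179 showed the reverse. A candidate explanation is that these loci are deleted from IR29 or too diverged for its reads to align to the reference, which these counts cannot tell apart from loci that are silent in IR29 roots or from a batch.

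Of the 10 splits of the libraries into 3 and 3, 1 gave as many loci as the split by cultivar, which is that split itself (1500 loci), and the highest of the others gave 0. The other splits leave the cultivar difference in the residual spread, and 6 of the 10 hold root types in unequal numbers, so that low counts were likely in them beforehand. These splits are too few for a share under 0.05.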
